A study of Mus musculus with 2 samples.

How the data were processed

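MicroRNA-seq had been carried out on midbrain of mouse embryos (Mus musculus, strain B6NCrl) at embryonic day 16.5. The 2 libraries were biological replicates of 1 group, each made from a pool of male and female embryos. Per the labels, the pool of replicate 2 held 37 embryos. The number of embryos behind replicate 1 was not given in the sources used here. Inserts were below 30 nt, a size class that holds mature microRNAs, the short RNAs cut from hairpin precursors that repress target mRNAs.

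The deposited values were raw counts of reads per miRNA gene, 1 table per library, on assembly mm10 with GENCODE annotation release M4, per the description deposited with the tables. The aligner, the counting program, their versions and the trimming of adapters were not given in the sources used here. Each table held 3 count columns, for reads on either strand, on the strand of the gene and on the opposite strand, and for every gene the last pair of columns summed to the first. Leading rows gave the reads that were unmapped, mapped to several places, fell in no gene or were ambiguous. That layout is the one of STAR's gene counts, in which a read is assigned to a gene only if it aligns to 1 place. This was read from the values and not from a statement of the authors.

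The rows that name no gene stayed out of library sizes and tests. Of 13638577 reads in replicate 1, 35.3% mapped to several places, 15.6% were unmapped and 3.99% fell in no gene on the sense strand. Of 12027645 reads in replicate 2, these shares were 36.5%, 15.2% and 4.14%. Reads on the sense strand of a miRNA gene numbered 6151299 in replicate 1 (45.1% of all reads) and 5312642 in replicate 2 (44.2%). Of the reads over miRNA genes on either strand, 2.56% and 2.49% lay on the opposite strand. Each table listed 1973 miRNA genes. Gene names and positions were taken from GENCODE M21, which is on the same assembly (GRCm38, mm10). By gene identifier, 1894 genes matched and 79 did not. The unmatched genes held 6 reads in each library. The list entries mir-219b, let-7e, mir-136, mir-299, mir-380, mir-376a, mir-376b, mir-409 and mir-142 were not analysed here. The place of a miRNA gene was called exonic or intronic from M21 genes on the same strand.

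Sense-strand counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), which were 1.02 for replicate 1 and 0.985 for replicate 2, and are given as CPM. A gene was called detected with 10 or more reads in both libraries. Log2 levels were log2(CPM + 1). Ratios are log2 of replicate 2 over replicate 1, with 0.5 reads added to each count, so a negative ratio is a higher level in replicate 1. Means are given with the SD over n = 2 libraries. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

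With 1 group there was no contrast between conditions. Replicate agreement was described by Pearson's r and Spearman's rho across genes, the SD of the log2 ratio and edgeR's biological coefficient of variation (BCV) from an intercept-only design. Intervals of r and of the SD came from 1000 bootstrap draws of genes, and those of the BCV from 100. Each detected gene's reads were compared between the libraries with a two-sided exact binomial test with Benjamini-Hochberg adjustment at 0.05. That test compares the libraries, not conditions, and covers counting error only. An exact permutation test of 2 values against 2 cannot give a two-sided p below 0.333, so no such test was run between genes.

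Lists of miRNA genes, 13 in all, covered brain and neurons, the oligodendrocyte lineage, the let-7 and mir-99/100/125 families, the mir-17-92 clusters, the imprinted Dlk1-Dio3 domain, the Hox clusters, and cells of other tissues that a dissection could bring along. For each list the median log2 CPM was placed among 10000 random lists of the same size, drawn from genes with a symbol and at least 1 read. The median log2 ratio of detected members was placed among 10000 random lists matched on mean level in 10 bins. These percentiles describe the libraries and are not p-values. Genes whose symbol carries a copy number, and of which another copy was analysed, were compared with the other matched genes. Mirlet7f-2 and Mir1a-1, for example, had no other copy analysed and counted among the others. The design, the lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule named the 20 genes with the highest mean CPM and, in each list, the 4 highest members and any member with 0 reads in both libraries. It also named the 10 genes with the largest ratio among those at 100 CPM or more, and all numbered copies of mir-124, mir-9, mir-128 and let-7. Genes named outside this rule are said to be so where they appear. The genes tied with another hairpin by near-identical sequence, such as the let-7 and mir-124 copies, have uncertain counts, since their shared reads can be left out.

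The binomial test was tested on simulated data for the 411 detected genes, 200 of them changed. With counting error only it called 98% of genes changed 4-fold, 84% of those changed 2-fold, 74% at 1.5-fold and 36% at 1.1-fold, and 1.90% of unchanged genes. With the estimated BCV added it called 57.8% of unchanged genes, so its calls do not account for variation between pools. In the list step, 88 of 100 simulated pairs placed a list of 15 genes shifted by -0.4 outside the central 95%, and 7 of 100 did so for an unshifted list. The simulated lists were random genes that varied independently. Hairpins of 1 genomic cluster had alike ratios in these libraries, so a list made of clusters can fall outside more often than these rates show. Alternatives were the count column for either strand, DESeq2's size factors (RLE in edgeR), no scaling, no read minimum, a minimum of 50, each replicate left out, other pseudocounts, other backgrounds, numbered copies left out, and edgeR's exact test at a fixed BCV of 0.2. The BCV of 0.2 was a set value and not a spread measured between these pools, as that test compares 1 library with 1 library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A gene with 0 reads may have up to 0.480 CPM in replicate 1 and 0.574 CPM in replicate 2, the level of 3 reads. This floor holds only for genes whose reads align to 1 place. It does not bound the level of genes that share a long run with another hairpin, such as Mir133a-1, Mir344 and Mir196a-1.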

Results

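The series measured miRNA levels in the midbrain of mouse embryos at day 16.5 of gestation, in 2 libraries from separate pools of embryos. Reads on the sense strand of miRNA genes numbered 6151299 in replicate 1 and 5312642 in replicate 2. As there was 1 group, the questions were which miRNA genes were abundant, and how far the libraries differed. Values are TMM-normalised CPM, mean ± SD over n = 2 unless stated.

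A few genes held most miRNA reads, meaning the sense-strand reads counted to miRNA genes. Reads that mapped to several places, 0.78 and 0.83 times as many in replicates 1 and 2, are left out. They can hold miRNAs of several copies, so the ranks and shares cover the counted reads only. Mir99a was the most abundant at 202107 ± 12354 CPM, followed by Mirlet7g at 70638 ± 5552, Mir335 at 49728 ± 1936, Mir487b at 41430 ± 3509, Mir100 at 35245 ± 621 and Mirlet7i at 34003 ± 3316. The gap between Mir99a and Mirlet7g exceeded the SD of either gene, whereas Mir100 and Mirlet7i lay within 1 SD of Mirlet7i of each other. Mir130a (29237 ± 2087 CPM), Mir149 (25511 ± 1455), Mir99b (24265 ± 142) and Mir126a (23955 ± 1761) completed the first 10. The remaining 10 of the first 20 were Mir30e, Mir17, Mir26b, Mir181c, Mir137, Mir135b, Mir30a, Mir127, Mir369 and Mir23b, from 22941 ± 365 down to 9669 ± 658 CPM. The 10 most abundant genes held 52.8% of miRNA reads in replicate 1 (95% Wilson interval 52.7 to 52.8) and 54.5% in replicate 2 (54.4 to 54.5). Mir99a alone held 19.6% (19.6 to 19.7) and 20.8% (20.7 to 20.8). With 10 or more reads in both libraries, 411 of the 1973 genes were detected (20.8%).

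**Figure D1:**
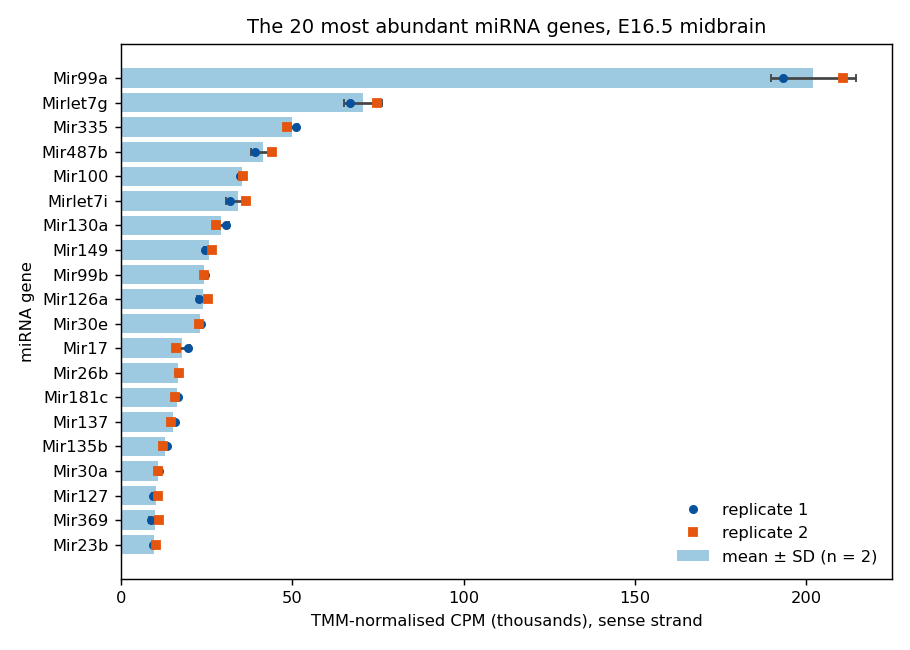
Mean TMM-normalised CPM of the 20 most abundant miRNA genes (bars, with SD over 2 libraries) and the value of each replicate (points). Mir99a, at 202107 CPM, lay above Mirlet7g at 70638 CPM in both libraries.

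Several of these genes lie inside longer transcripts of the mm10 assembly, as annotated in GENCODE M21. Mir99a (ENSMUSG00000065530.1, chromosome 16, 77598936 to 77599000) is in an intron of Mir99ahg. Mirlet7g (chromosome 9, 106178840 to 106178927) is in an intron of Wdr82, and Mir335 (chromosome 6, 30741299 to 30741396) in an intron of Mest, an imprinted gene expressed from the paternal allele. Mir149 (chromosome 1, 92850378 to 92850443) is in an intron of Gpc1. Mir126a (chromosome 2, 26591357 to 26591429) overlaps an exon of Egfl7, a gene of endothelial cells. Mir17 (chromosome 14, 115043671 to 115043754) overlaps an exon of Mir17hg. Mir487b (chromosome 12, 109727333 to 109727414) lies between annotated genes of its strand, in the imprinted Dlk1-Dio3 domain.

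The let-7, mir-98, mir-99, mir-100 and mir-125 list, whose let-7 members accumulate as cells differentiate, held 39.9% ± 1.67 of miRNA reads, with all 16 of its genes detected. The imprinted Dlk1-Dio3 domain held 11.3% ± 0.40, with 40 of 41 genes detected. Mir487b led it, then Mir127 at 10111 ± 1038 CPM, Mir369 at 9809 ± 1692 and Mir382 at 8336 ± 508, and Mir654 had 0 reads. The brain and neuron list held 8.12% ± 0.14, with 26 of 30 genes detected, led by Mir149, Mir137 (15098 ± 738 CPM), Mir135b (12819 ± 713) and Mir153 (5865 ± 258). Mir344 and Mir344-2 had 0 reads. Each shares 39 bases with another hairpin, so reads of either can be left out and 0 reads does not show absence. The mir-17-92 list, whose clusters promote proliferation of progenitor cells, held 4.75% ± 0.83, led by Mir17 (17655 ± 2553 CPM), Mir93 (8663 ± 840), Mir106b (8304 ± 1277) and Mir20a (6158 ± 1391). The oligodendrocyte list held 0.161% ± 0.012, with Mir219a-2 at 925 ± 124 CPM, Mir338 at 422 ± 55.8 and Mir219a-1 at 267 ± 19.5.

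In the vessel and mesenchyme list (3.47% ± 0.091 of reads), Mir126a, a miRNA of endothelial cells, was followed by Mir143 at 6032 ± 59.7 CPM, Mir140 at 4359 ± 29.6 and Mir214 at 157 ± 1.77. In the eye, sensory organ and choroid plexus list (0.359% ± 0.0095), Mir204, a miRNA of choroid plexus and retinal pigment epithelium, stood at 2227 ± 253 CPM, Mir183 at 596 ± 132, Mir182 at 543 ± 73.8 and Mir96 at 199 ± 32.4. The Hox list (0.120% ± 0.0020) was led by Mir10a at 720 ± 28.4 CPM and Mir10b at 438 ± 27.9, with Mir615 at 29.0 ± 4.25, Mir196b at 16.4 ± 5.95 and Mir196a-1 at 0 reads. In the liver, gut and pancreas list (0.0925% ± 0.0028) Mir375 stood at 361 ± 30.6 CPM, Mir217 at 208 ± 20.5, Mir192 at 91.1 ± 1.70 and Mir194-2 at 75.1 ± 6.33. In the blood list (0.0543% ± 0.0051) the erythroid Mir451a stood at 151 ± 44.4 CPM, the myeloid Mir223 at 138 ± 6.90, Mir150 at 90.4 ± 17.4 and Mir144 at 69.9 ± 4.54. The pluripotent cell list (0.0652% ± 0.015) was led by Mir302a at 246 ± 54.0 CPM, Mir302d at 219 ± 33.5, Mir302b at 150 ± 43.6 and Mir302c at 21.98 ± 3.77, with Mir367 and Mir290a at 0 reads. The muscle and heart list held 0.00398% ± 0.00014. Its highest members were Mir206 (17.9 ± 0.033 CPM), Mir208b (15.9 ± 0.84), Mir499 (3.78 ± 0.60) and Mir208a (1.48 ± 0.063), while Mir133a-1, Mir133a-2 and Mir1a-1 had 0 reads. Mir133a-1 and Mir133a-2 each share 31 bases with another hairpin, and Mir1a-1 shares 28. Their reads can be left out as mapping to several places, so neither the 0 reads nor the list's share shows that muscle miRNAs were absent. These shares and orders leave out list entries not analysed as genes. At their places, reads counted opposite another gene came to 237 CPM for Mir142 of the blood list and 6454 CPM for Mirlet7e. In the Dlk1-Dio3 domain they came to 5945 CPM for Mir376a, 5561 for Mir409, 912 for Mir380 and 679 for Mir299a, all chosen after their values were seen.

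Against random lists of genes with at least 1 read, 5 of the 13 lists had a median above the 95th percentile. These were the brain list (median 478 CPM), the let-7 list (4805 CPM) and the Dlk1-Dio3 domain (833 CPM), each at 100, the mir-17-92 list (349 CPM) at 99.6 and the eye and sensory organ list (327 CPM) at 96.8. The others stood at 93.7 for vessel and mesenchyme, 91.4 for liver, gut and pancreas, 91.0 for oligodendrocytes, 88.5 for blood, 81.3 for epithelium, 75.0 for Hox, 54.0 for pluripotent cells and 53.0 for muscle and heart. With numbered copies left out, the vessel and mesenchyme list stood at 99.02 and 6 lists lay above the 95th percentile. Without replicate 2 the eye and sensory organ list stood at 94.95 and 4 lists lay above the 95th percentile. The background moved the count more. Against detected genes alone, a choice made after seeing the data, 3 lists stayed above the 95th percentile, with the brain list at 99.2, the let-7 list at 100 and the Dlk1-Dio3 domain at 99.98. The mir-17-92 list then stood at 87.8 and the eye and sensory organ list at 77.6.

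The replicates ranked the genes nearly alike. Across the 411 detected genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.994 (bootstrap interval 0.992 to 0.996) and Spearman's rho was 0.990. The log2 ratio had an SD of 0.43 (0.36 to 0.52) and its median size was 0.18. Of 91 genes at 1000 CPM or more, all 91 lay within 1.5-fold between the libraries, as did 205 of 210 genes at 100 CPM or more. The common BCV was 16.9% (12.9 to 21.1), and along the trend with abundance it ran from 9.38% to 22.9%. A chi-square over its 410 degrees of freedom was 85.8, so the tables were not copies of 1 library within sampling noise and were counted as 2 samples. This says nothing about the size of the difference between the pools.

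The mir-200 family showed the widest gap between the libraries. Mir429 (chromosome 4, 156053905 to 156053987), of the mir-200 family that maintains epithelial identity, stood at 413 CPM in replicate 1 and 60.4 CPM in replicate 2 (6.83-fold). Its neighbour Mir200b stood at 104 and 17.8 CPM (5.81-fold), and Mir200c on chromosome 6 at 88.0 and 32.5 CPM (2.70-fold). All 7 genes of the epithelium list were higher in replicate 1 by the exact binomial test, and 7 when adjusted over the list alone, while 4 were at a fixed BCV of 0.2. Mir203, the most abundant at 586 ± 44.4 CPM, had a log2 ratio of -0.15. The list's median ratio was -2.31, at percentile 0 of random lists matched on abundance, and the percentile was 0 under each scaling tried. With a minimum of 50 reads 5 of its genes entered and the median was -1.42, still at percentile 0.

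The mir-17-92 list was lower in replicate 2 and the let-7 list higher. In the mir-17-92 list 14 of 15 genes had ratios below 0, with a median of -0.41 at percentile 0 of the random lists. By the exact binomial test 13 were higher in replicate 1 and 0 in replicate 2 (14 and 0 adjusted over the list alone). Examples were Mir17 at -0.30, Mir20a at -0.46, Mir106a at -0.71 and Mir20b at -0.74. In the let-7 list 13 of 16 genes had ratios above 0, with a median of 0.20 at percentile 99.98. There 13 were higher in replicate 2 and 2 in replicate 1 (13 and 3 adjusted over the list alone). With edgeR's exact test at a fixed BCV of 0.2, which allows for spread between pools, each detected gene of both lists had an adjusted p of 1. Mirlet7i had a ratio of 0.20, Mirlet7c-2 of 0.42 and Mirlet7a-1 of 0.44. The pluripotent cell list also had a median of -0.35, at percentile 1.24, with all 7 detected genes below 0, of which 3 passed the test (3 adjusted over the list alone), namely Mir302a, Mir302b and Mir302d, and 0 at the fixed BCV.

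**Figure D2:**
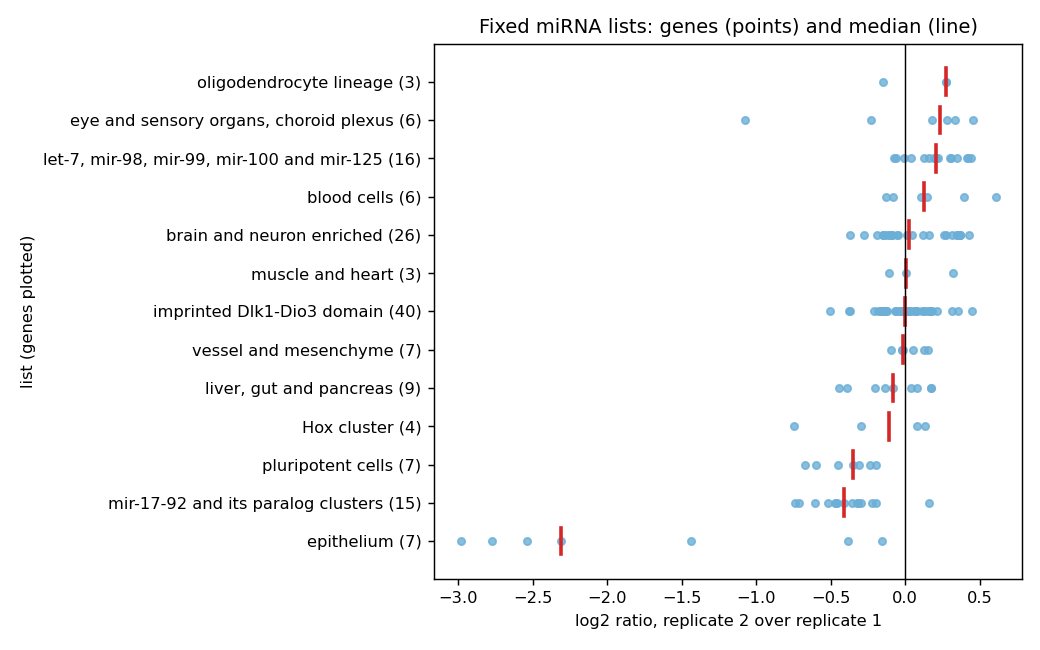
Log2 ratio of replicate 2 over replicate 1 for each detected gene of the 13 lists (points) with the median of the list (line) and the number of genes in brackets. The epithelium list has a median of -2.31 and the mir-17-92 list of -0.41, while the let-7 list lies at 0.20.

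The other 9 lists lay inside the central 95% of random lists. The brain list had a median ratio of 0.03, which turned to -0.02 without scaling and to -0.06 with numbered copies left out. It held 11 genes higher in replicate 2, 8 higher in replicate 1 and 7 that did not pass (11 and 8 adjusted over the list alone). The Dlk1-Dio3 domain had a median of -0.003, which turned to 0.007 with RLE size factors, with 10 genes higher in replicate 2 and 11 in replicate 1 (11 and 11 adjusted over the list alone). For the eye and sensory organ list 3 genes, Mir183, Mir182 and Mir96, were higher in replicate 2 and 2 higher in replicate 1 (3 and 2 adjusted over the list alone). The counts higher in replicate 2 and in replicate 1 were 2 and 1 for oligodendrocytes, 2 and 1 for Hox, 2 and 0 for blood, 1 and 3 for liver, gut and pancreas, 1 and 0 for vessel and mesenchyme, and 0 and 0 for muscle and heart. Adjusted over the list alone, these 6 lists gave the same counts. At the fixed BCV, 0 genes of these 9 lists passed.

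Over all detected genes, 185 differed by the exact binomial test, 97 higher in replicate 1 and 88 in replicate 2. With a fixed BCV of 0.2 in edgeR's exact test 5 genes did. Of those, named after their values were seen where the rule did not take them, Mir429, Mir200b, Mir200a and Mir141 were higher in replicate 1 and Gm23935 (chromosome 16, 11144125 to 11144181) in replicate 2, with Gm23935 at 41.6 and 121 CPM. At least 2-fold, 10 genes differed, 7 higher in replicate 1 and 3 in replicate 2. Among genes at 100 CPM or more, the largest ratios after Mir429 were those of Mir20b and Mir106a, then Mir451a at 0.61, Mir302b at -0.60, Mir346 (in an intron of Grid1) at 0.53, Mir494 at -0.50, Mir1251 (in an intron of Rmst) at -0.49, Mir20a and Mir363 at -0.46.

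**Figure D3:**
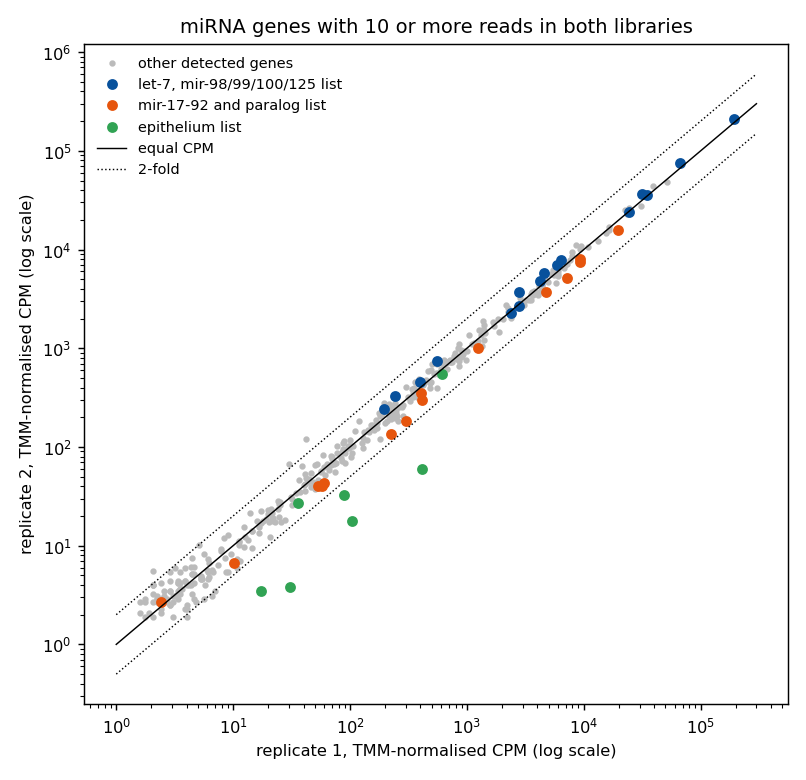
TMM-normalised CPM of the 411 detected genes in replicate 1 and replicate 2 on log axes, with 3 lists in colour, the line of equal CPM and dotted lines at 2-fold. Genes of the mir-200 family lie below the lower dotted line, among them Mir429 at 413 and 60.4 CPM.

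Genes annotated as numbered copies were not lower as a class. Of 113 such genes 40.7% were detected, against 20.5% of the other 1781 matched genes, and the medians of detected genes were 226 and 104 CPM. The log2 difference between these medians was 0.52 without replicate 2, where detection was called in replicate 1 only. The 1781 other genes include those without a Mir symbol. Medians over detected genes also leave out copies with few or no reads. These values therefore do not show that the copies lost no reads. With copies recognised by sequence, chosen after seeing the data, and among genes with a Mir symbol alone, 37.6% of 226 sharing 20 bases with another hairpin were detected, against 38.7% of 825 sharing none. Within the brain list the families differed. The 3 mir-124 genes, copies of a miRNA known to be abundant in neurons, held 57 and 51 reads in replicates 1 and 2, at 3.15 CPM per copy. Mir124a-1 stood at 5.03 ± 0.35 CPM, Mir124a-2 at 3.86 ± 0.48 and Mir124a-3 at 0.54 ± 0.31. Mir9-3 stood at 406 ± 68.5 CPM and Mir9-2 at 1.33 ± 1.07. Mir128-1 stood at 2460 ± 441 CPM and Mir128-2 at 1400 ± 186. The let-7 copies Mirlet7c-2, Mirlet7c-1, Mirlet7a-1 and Mirlet7a-2 stood at 645 ± 132, 429 ± 43.6, 284 ± 60.7 and 219 ± 33.0 CPM, and Mirlet7f-2, named after its value was seen, at 3226 ± 649. Reads listed as mapping to several places made up 35.3% and 36.5% of all reads.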

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

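The tests of the run of bases shared by the mir-124 hairpins and of shared bases among the most abundant genes were chosen only after the mir-124 counts were seen, and the genes named for their opposite-strand reads were chosen after their values were seen.

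Reads on the strand opposite the annotated gene were not used in any comparison above and numbered 100 or more in each library at 11 genes. These 11 held 99.8% of opposite-strand reads in each library. Summed over both libraries, there were 73986 reads opposite Gm25927, 68448 opposite Gm25252, 63885 opposite Gm24321, 38184 opposite Gm24083 and 23867 opposite Gm25301. There were 10491 opposite Gm25750, 7858 opposite Mir299b, 5452 opposite Mir497b, 2723 opposite Mir142b, 1091 opposite Gm24111 and 234 opposite Gm25641. At each of the 11, GENCODE M21 places a miRNA gene on the other strand that was not analysed here as a gene of its own. In the same order these are Mirlet7e, Mir376a, Mir409, Mir191, Mir378a, Mir380, Mir299a, Mir497, Mir142, Mirlet7f-1 and Mir9-1. Counted as a gene, the reads opposite Gm25927 (chromosome 17, 17830343 to 17830459) would have a mean of 6454 CPM and rank 30. A further 10 genes had more than 3 opposite-strand reads in each library, 487 reads in all, the most at Mir3074-1 with 89 and 59.

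Reads that mapped to several places were also outside the comparisons, at 4816290 in replicate 1 and 4391928 in replicate 2. Low counts of the mir-124 genes, at 3.15 CPM per copy and percentile 7.95 of detected single-copy genes, may come from such reads being left out. The 3 mir-124 hairpins share a run of 31 bases, longer than the inserts of below 30 nt. A read inside that run cannot align to 1 place. The analysed hairpins of mir-9 (26 bases) and of mir-128 (23 bases) also share a run. Inserts can reach past it, but a read inside it cannot align to 1 place either. These families stood at percentiles 57.3 and 81.1. The former was carried by Mir9-3 (406 CPM), while Mir9-2 stood at 1.33 CPM, as low as the mir-124 copies. Mir9-2 shares a run of 33 bases with another hairpin, also longer than the inserts, so its reads can be left out too. Of the 20 most abundant genes 2 share 20 or more bases with another hairpin, against 89 of the 411 detected genes of any symbol, which lies between the bounds set for and against a loss of shared reads. If only reads at 1 place were counted, as the layout implies, reads inside the mir-124 run were lost from the gene counts. Whether mir-124 was also low cannot be told, since the reads that mapped to several places are not listed by gene. No biological explanation was tested.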

How the results depend on the processing

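The alternatives that left out the mir-200 family, used detected genes as background, recognised copies by shared bases or left numbered copies out of the list ratios were chosen after seeing the data. Of 62 alternatives of the main results 50 stayed within the bounds set for a like value, 12 moved and 0 reversed; for single lists 132 of 180 stayed, 48 moved and 0 reversed, where a reversal was counted only for ratios of the 4 lists outside the central 95%. Medians near 0 of other lists, such as brain, Hox and Dlk1-Dio3, changed sign under some alternatives. With no read minimum 750 genes counted as detected, the SD of the log2 ratio was 1.17, 22 genes differed at least 2-fold and the copies' difference in median log2 CPM (1.105) was 3.65, as genes with few reads entered. With a minimum of 50 the SD was 0.35 and 5 genes differed at least 2-fold, as fewer genes were tested. Without the mir-200 family 5 genes did. The share of the 10 most abundant genes was 52.3% on either strand against 53.6%, since that column adds reads. Above the 95th percentile lay 12 lists with all annotated genes as background and 3 with detected genes. At a fixed BCV of 0.2, which allows for spread between pools, 5 genes differed against 185. The copies' difference was 0.52 without replicate 2 and 1.29 without replicate 1, with detection called in the kept library only. Over the genes detected in both libraries, the median log2 CPM in replicate 1 was 7.69 for copies and 6.72 for the others. The fall to 0.52 thus came in part from the genes that entered. Leaving out 1 replicate also gave 426 to 444 detected genes, 52.8% to 54.5% for the share of the 10 most abundant, and 4 to 5 lists above the 95th percentile. The read minimum does not enter the lists' abundance percentiles, so other minimums say nothing about them. Under each alternative run, 4 lists had median ratios outside the central 95%. No paired analysis was possible because the series holds 1 group. At this depth, genes with fewer than 10 reads were not compared.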

Other observations

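The genes named here outside the naming rule were chosen after their values were seen, as were the tests of counting error, of reads moved within the mir-200 family, of epithelial tissue, of the mir-17 seed and of the share of neurons. The tests on GC content and on neighbouring hairpins were written before their results were seen.

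Inside the brain list, members had ratios of either sign. By the exact binomial test 11 genes were higher in replicate 2 and 8 in replicate 1. The largest ratios among the 11 were those of Mir129-2 (log2 ratio 0.43), Mir132 and Mir212, which respond to neuronal activity (both 0.37), Mir128-1 (0.37), Mir138-1 (0.35), Mir383 (0.35) and Mir9-3 (0.35). Among the 8, the largest were those of Mir7-1 (-0.37), Mir7-2 (-0.28), Mir7b (-0.15), Mir135a-1 (-0.19) and Mir708 (-0.15). The list's 4 most abundant members also passed, with smaller ratios. These were Mir149 (0.12), Mir137 (-0.10), Mir135b (-0.11) and Mir153 (-0.09). The list as a whole had a median of 0.03. These calls cover counting error only, as do those of 45.0% of all detected genes, and with edgeR's exact test at a fixed BCV of 0.2 each of these genes had an adjusted p of 1.

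The 5 mir-200 family genes, Mir429, Mir200a, Mir200b, Mir200c and Mir141, summed to 653 CPM in replicate 1 and 118 CPM in replicate 2. The tables argue against counting error, since all 5 genes passed the exact binomial test, and against reads moved between hairpins of the family, since the summed level itself had a log2 ratio of -2.47. Epithelial tissue in the pool of replicate 1 may account for it, but Mir203 (-0.15) and Mir205 (-0.38), the list's other members, had a median of -0.27, and each lay within 1 SD of the ratio over detected genes (0.43). All 7 list genes were detected in both libraries, with Mir203 the most abundant at 586 CPM. The test leaves epithelial tissue open, and the labels give no condition that differs between the pools.

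The mir-17-92 list was lower and the let-7 list higher in replicate 2, with medians 0.61 apart. A scaling factor per library cancels in this gap, so scaling was not tested. Bias tied to the mir-17 seed would leave members with another seed near 0. The median of those 9 was -0.41, against -0.39 for the 6 members with the seed. This argues against the seed as the only source. That 8 of 9 lay below 0 followed from 14 of 15 in the list and adds nothing. After a linear trend on hairpin GC was removed, the gap was 0.60. Hairpin GC tracked the ratio weakly across genes (Pearson's r 0.09). These values argue against hairpin GC only, as GC of the short inserts was not tested. A larger share of neurons in the pool of replicate 2 may be involved, but the brain list's median lay at percentile 75.8, or 15.4 with numbered copies left out, with members on both sides of 0, which decides nothing. A difference in stage or dissection between the pools stays open and was not tested.

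Hairpins of 1 genomic cluster may deviate together between the libraries. Over 310 pairs of detected hairpins within 10000 bp on 1 strand that share no run of 12 bases, the log2 ratios differed by 0.23 on average, against a median of 0.46 when ratios were shuffled over the 138 clustered genes. None (0) of 10000 shuffles gave so small a value, percentile 0.01, the smallest they can give. Without the mir-200 and mir-17-92 lists, 277 pairs gave 0.23 against 0.28, percentile 2.32. Without the Dlk1-Dio3 list, 92 pairs gave 0.29 against 0.56, percentile 0.01, so most of the 310 pairs involved that domain. These lists were not all left out together, and the shuffles were not matched on abundance. That hairpins of 1 cluster deviate together is a hypothesis from 2 libraries. A shared primary transcript is a candidate source that was not tested.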
